A study of Mus musculus with 58 samples.

How the data were processed

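Lungs of 29 male C57BL/6JRj mice were profiled, with 1 mRNA library and 1 miRNA library per animal, 58 libraries in all. Per the labels' protocols, mice were randomized, young mice received 0.7 mg/kg and old mice 0.63 mg/kg bleomycin sulphate into the trachea on 1 occasion, and control mice of both ages received saline. On day 21 the lungs were perfused with buffer, the lobes were frozen and powdered, and total RNA was extracted from 20 mg of frozen powder with the Qiazol procedure. The labels call the mice young or old without giving an age in weeks. They give each animal an id, so the mRNA and the miRNA library of an animal could be matched. Groups were taken from the labels, and animals were numbered within a group in the order of their records, so a number names an animal and pairs nothing across groups. The labels give no sequencing batch. Animal ids of young and old mice do not overlap, so any difference in the time of handling is confounded with age, and age is confounded with dose among bleomycin mice. The proteomic data that the series title mentions were not used here.

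The mRNA values were deposited by the authors as RPKM, reads per kilobase of gene per 1e6 mapped reads, for 38202 Ensembl genes, per the file headers and the values themselves. The submitters' processing notes list STAR 2.5.2a, FastQC 0.11.2, Subread 1.5.0 with featureCounts, Cufflinks 2.2.1, limma and the mouse build GRCm38, without saying what each was used for. The gene annotation, the library kit and whether reads were counted by strand are not given in the sources used here. Values of genes that overlap on opposite strands are therefore uncertain, and near-identical paralogues such as Hspa1a and Hspa1b cannot be told apart with certainty. RPKM divide each library by its own total, so a change in a very abundant transcript moves the share left for all others: the most abundant gene of a library, Scgb1a1 in each library but old bleomycin replicate 9 (Sftpc), took between 4.24% (mean of old bleomycin mice) and 9.39% (mean of young saline mice) of the summed RPKM. Symbols from the reference table were matched to 36340 of the 38202 identifiers; 1862 had none, 1 was not an Ensembl gene, and 8 shared a symbol with another identifier. Gene positions come from a RefSeq table of assembly GRCm38.p6 that carries no strand.

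The miRNA values were deposited by the authors as reads per mature miRNA for 1900 miRNAs. They are not all whole: 85.0% of values, and 68.1% of those above 0, were whole within 0.001, and the fractions were mostly simple ratios. The deposited values were therefore taken to be expected counts, judged from the values themselves, and were rounded before the count model. The labels do not state how reads shared by several miRNAs were assigned. Some miRNAs had nearly the same count in every library: 36 of the 519 tested miRNAs differed from another by a mean relative difference under 0.02, among them miR-126a and miR-126b arms, miR-24-3p and miR-3074-5p, and miR-374b-5p and miR-374c-3p. Such pairs cannot be told apart, and their reads enter the totals more than once. With 1 kept of each set 500 miRNAs remained, and 239, 246, 0, 43 and 69 passed in the 5 comparisons, against 249, 256, 0, 43 and 73 with all kept.

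Depth was between 5.39 and 10.73 M miRNA reads (M, 1e6) per library. Group means were 8.92 M in young saline, 8.82 in young bleomycin, 8.05 in old saline and 6.97 in old bleomycin mice. RPKM carry no total, but low values of a gene are whole multiples of what 1 read is worth. Over 907 genes with values above 0 in 4 to 10 libraries, 93.5% of values were whole within 0.05 of a read, and the relative depth of the mRNA libraries came out between 0.818 and 1.211, with group means between 0.914 and 1.025. The absolute mRNA depth is unknown, so no counting interval was computed. No pair of libraries held identical values (0 of 406 in either assay). Within groups, Pearson r between libraries was between 0.9516 and 0.9903 for mRNA and between 0.9755 and 0.9964 for miRNA.

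For mRNA, genes with an RPKM of at least 0.5 in at least 5 libraries were kept (16012), and log2(RPKM + 0.5) was tested with limma 3.58.1 (trend and robust empirical Bayes) in a model with a mean for each of the 4 groups, fitted over all 29 libraries without further scaling. Fold changes are on that scale, which understates the change of low genes. The 4 groups share 1 estimate of the spread of a gene, so a test between saline mice also draws on the spread of bleomycin mice. For miRNA, those with a count of at least 10 in at least 5 libraries were kept (519) and tested with the quasi-likelihood test of edgeR 4.0.16 after TMM normalization, in the same model. In both assays 5 comparisons were made: bleomycin against saline in young and in old mice, the difference between those effects, and old against young mice given saline or given bleomycin. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05 and no fold minimum. An adjusted p in the report is limma's for a gene and edgeR's for a miRNA, over all genes or miRNAs tested. In the same text a change is a log2 fold change ± its standard error (SE), and a level is a group mean ± SD. The edgeR test gives no SE, so that of a miRNA was worked back from its log2 fold change and test statistic.

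Before the data were examined, 33 lists of genes for lung cell types, matrix, injury, stress and neighbouring tissues, and 12 lists of miRNAs, were written down. Each was tested with limma's camera at its preset inter-gene correlation of 0.01, on log2(RPKM + 0.5) or on log2 CPM with a prior count of 2, and with Benjamini-Hochberg over the lists. Lists with fewer than 3 tested members were to be left out, and none fell under that limit. As alternatives, camera was run with a correlation estimated from the data and fry was run, which tests whether members move one way and does not compare a list with other genes. Camera with the preset correlation called lists for other splits of the same animals about as often as for the real groups, so the report describes lists by the number of members past the gene test. An extracellular matrix score per animal, the mean log2(RPKM + 0.5) of the 32 tested matrix genes, was compared by exact two-sided permutation tests (all 2002, 5005 and 48620 splits) and, for the difference of the effects, by 100000 resamples. Its relation to 4 miRNAs chosen in advance was tested in each bleomycin group by exact permutation of the pairings, adjusted over 8 relations.

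The genes named in the text follow a rule fixed in advance. It takes the 10 largest rises and 10 largest falls past the threshold for the 2 bleomycin comparisons and for age in saline mice, and 5 of each for the rest, with a mean RPKM of at least 1. Predicted, clone-named and immunoglobulin or T-cell receptor segment genes are given as a count. To these come up to 4 members of each list with the smallest p, and 16 genes in every comparison. For miRNAs it takes 10 of each for bleomycin, 5 of each otherwise, and up to 4 per list. Of the genes named by this rule, a single one is left out and is not reported here.

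Alternatives planned in advance were pseudocounts of 0.1 and 1, no filter and an RPKM minimum of 2, median-ratio scaling, quantile normalization, array weights, fits on the compared groups alone, and each library left out in turn. For miRNAs they were DESeq2 1.42.0, RLE size factors, library totals alone, no filter, a count minimum of 100, and voom with quality weights. A fit without the 6 animals with squamous or muscle transcripts was added after the data were seen. The gene and miRNA tests were tested on simulated values with 200 changed genes, and the list test on values with the 32 members of a list shifted by 0.5 on the log2 scale. For bleomycin in young mice the gene test recovered 68.7%, 89.6% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale. There 2.3% of its calls were unchanged genes, and the highest such share was 5.4%, for bleomycin in old mice. The list test called the shifted list in all 5 comparisons and at most 1 other list, on genes simulated to vary independently. For the difference between ages the shares were 52.2%, 92.5% and 100% for genes and 23.9%, 82.1% and 97.0% for miRNAs. With 200 changed genes the adjusted threshold is easier to pass. In the data 2 genes and 0 miRNAs passed for the difference, so the share found there may be lower. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.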

Results

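Gene expression and miRNA abundance were measured in whole lungs of 29 male mice, each a separate animal, 21 days after 1 dose of bleomycin or saline into the trachea. Bleomycin breaks DNA and, given into the airways of mice, is a common way to induce lung fibrosis. There were 5 young and 6 old mice given saline, and 9 young and 9 old mice given bleomycin. Each animal gave 1 mRNA library, with values in RPKM, and 1 miRNA library, with values as read counts. The miRNA libraries held between 5.39 and 10.73 M reads. Mean depth was 8.92 ± 1.18 M reads (SD, n = 5) in young saline, 8.82 ± 0.60 (n = 9) in young bleomycin, 8.05 ± 1.5 (n = 6) in old saline and 6.97 ± 1.07 (n = 9) in old bleomycin mice. Old bleomycin mice therefore had the shallowest miRNA libraries. The number of mRNA reads per library is unknown. Between 14666 and 15473 genes per mRNA library had an RPKM of at least 0.5. The first principal component took 35.4% of the variance of mRNA and 39.0% of that of miRNA.

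The first question was what bleomycin does in young lungs. Genes of fibrosis-associated macrophages rose most. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344397–7360461 in assembly GRCm38, counted from 1), a macrophage protease that degrades elastin, rose from 2.63 ± 0.605 RPKM (SD, n = 5) to 101 ± 31.2 (SD, n = 9), a log2 fold change of 4.98 ± 0.28 (SE; adjusted p = 1.7e-13). Spp1 (ENSMUSG00000029304, chromosome 5, 104435111–104441053), which encodes the matrix phosphoprotein osteopontin, rose from 75.1 ± 16.5 to 1428 ± 226 RPKM, a log2 fold change of 4.26 ± 0.17 (SE; adjusted p = 7.1e-17). Each was higher in 9 of 9 bleomycin mice than in any saline mouse. Matrix genes rose with them: Col1a1 (chromosome 11, 94936224–94953042), the main fibrillar collagen chain, rose by 1.88 ± 0.31 from 113 ± 8.34 to 439 ± 140 RPKM, Col3a1 by 1.44 ± 0.21 and fibronectin, Fn1, by 2.81 ± 0.28.

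The other large rises were the acute-phase gene Saa3 (4.77 ± 0.44), the alternative-activation gene Retnla (3.81 ± 0.37), the macrophage receptors Trem2 (3.55 ± 0.11) and Msr1 (3.24 ± 0.18), the matrix gene Tnc (3.47 ± 0.35), the BMP antagonist Grem1 (3.34 ± 0.39), the protease inhibitor Timp1 (3.29 ± 0.40) and the hyaluronan-degrading Cemip (3.29 ± 0.46). The largest falls were in Bex2 (−2.95 ± 0.24, from 26.6 ± 4.02 to 3.07 ± 0.981 RPKM), Cyp1a1 (−2.93 ± 0.55), Cst8 (−2.85 ± 0.27), Colq (−2.83 ± 0.30), Slc7a10 (−2.64 ± 0.34), Krt79 (−2.61 ± 0.30), Gria1 (−2.45 ± 0.26), Mb (−2.44 ± 0.77), Hes2 (−2.32 ± 0.14) and Fabp1 (−2.30 ± 0.30). Cyp1a1, an enzyme induced by aromatic hydrocarbons, and Mb, the myoglobin of muscle, each had 1 young saline mouse far above the others, replicate 3 for Cyp1a1 and replicate 1 for Mb. Arg1 (2.86 ± 0.45), Cthrc1 (1.40 ± 0.33), the keratin Krt8 (0.70 ± 0.09) and the cell-cycle inhibitors Cdkn1a (0.78 ± 0.10) and Cdkn2a (1.92 ± 0.17) rose. Acta2, the smooth-muscle actin of myofibroblasts, did not pass (−0.19 ± 0.17, adjusted p = 0.39), nor did the alveolar type 1 gene Ager (0.17 ± 0.10, adjusted p = 0.15). Gdf15 rose by 0.38 ± 0.13 (adjusted p = 0.02), but not in a fit with only the compared groups (0.0694) or without the 6 animals with squamous or muscle transcripts (0.123). The surfactant gene Sftpc fell by 0.51 ± 0.19 (adjusted p = 0.03). It has one of the highest values of all genes, and it did not pass under quantile normalization or without those 6 animals (0.0772).

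Of 16012 genes, 7715 passed in young mice at an adjusted p under 0.05, 3495 higher and 4220 lower, and 788 of them changed at least 2-fold. With median-ratio scaling 3878 were higher and 3795 lower, so the excess of lower genes depended on scaling. Of 100 splits of the same animals with the real one included, no other gave more than 3253. Of 176 immunoglobulin and T-cell receptor segments 10 passed, 7 of them higher.

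Marker genes of cell types and programmes were counted in lists fixed in advance. Of 32 matrix genes 28 were higher and 0 lower (28 adjusted over the list alone), among them Sparc (1.17 ± 0.10) and elastin, Eln (2.57 ± 0.27). Of 22 genes of fibrosis-associated macrophages 19 were higher and 1 lower (20 over the list alone), with Gpnmb at 3.09 ± 0.12. Of 18 genes of the Krt8-type transitional epithelium, the state between alveolar type 2 and type 1 cells, 17 were higher, among them Lgals3 (1.42 ± 0.09), Clu (1.1 ± 0.11) and Cldn4 (2.65 ± 0.28). Of 22 cell-cycle genes 20 were higher and 1 lower, with Cdk1 at 1.57 ± 0.20 and Ube2c at 1.16 ± 0.17. Camera called all 4 lists, with adjusted p = 1.34e-13, 8.68e-17, 1.81e-10 and 1.55e-08 at its preset correlation. With an estimated correlation of members camera gave 0.272, 0.0634, 0.0634 and 0.257, so none held in camera. Fry, which does not compare a list with other genes, gave adjusted p = 2.07e-06, 1.56e-14, 6.27e-11 and 1.48e-06. It called each of the 18 lists that camera called in young mice at its preset correlation.

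In 6 further lists more members rose than fell in young mice, and some members of each did not pass. Contractile and activated fibroblast genes had 15 of 22 higher and 2 lower, with Igf1 at 2.17 ± 0.17, Tgfbi at 1.33 ± 0.14 and the smooth-muscle gene Cnn1 at −1.25 ± 0.17. Complement and acute-phase genes had 12 of 16 higher and 2 lower, with Lcn2 at 2.14 ± 0.11 and Lrg1 at 2.08 ± 0.12. Interferon genes had 10 of 20 higher and 1 lower, with Cxcl10 at 2.08 ± 0.27 and Isg15 at 0.89 ± 0.17. Genes of p53 targets had 14 of 18 higher and 1 lower, with Psrc1 at 2.26 ± 0.15 and Ccng1 at 0.73 ± 0.05. Senescence genes had 16 of 21 higher and 1 lower, Igfbp3 falling by 2.02 ± 0.16. MHC class II genes had 7 of 11 higher and 1 lower, with Ctss at 2.59 ± 0.12 and H2-Eb1 at 0.74 ± 0.15. Adjusted over the list alone, 17, 14, 11, 16, 18 and 9 members of these lists passed. Camera called each of the 6, from adjusted p = 9.3e-07 for p53 to 0.00796 for MHC class II, and with an estimated correlation all were at 0.257 or above.

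Many genes of the lung's own vessels and airways fell in young mice, although 9 of 15 club-cell genes did not pass. Over all genes 4220 of 16012 were lower. General capillary genes had 11 of 15 lower, with Kdr at −0.98 ± 0.11 and Tek at −0.79 ± 0.09, and genes of aerocytes, the capillary cells of gas exchange, had 9 of 10 lower, with Ednrb at −1.54 ± 0.16 and Fibin at −1.22 ± 0.13. Ciliated-cell genes had 15 of 16 lower, with Tppp3 at −1.43 ± 0.25 and Rsph4a at −0.84 ± 0.25, and club-cell genes 6 of 15 lower, with Cbr2 at −1.43 ± 0.22 and Scgb1a1 at −1.05 ± 0.22. Lipofibroblast genes had 10 of 14 lower and 3 higher, with Inmt at −2.01 ± 0.21 and Itga8 at −0.99 ± 0.12. Immediate early and heat-shock genes had 10 of 16 lower and 3 higher, with Jun at −0.64 ± 0.07 and Dusp1 at −0.96 ± 0.13. Adjusted over the list alone, 11, 9, 16, 6, 13 and 15 passed. Camera called these 6 lists, from adjusted p = 2.94e-06 for aerocytes to 0.0156 for club cells, and with an estimated correlation all were at 0.257 or above.

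Squamous and skeletal-muscle transcripts were high in a few libraries. The squamous keratin Krt13 was at 840, 770, 265, 369 and 1985 RPKM in young saline replicate 1, young bleomycin replicate 7, old bleomycin replicates 2 and 3, and old saline replicate 4, and at most 2.56 in the other 24 animals. The same 5 had skeletal-muscle actin, Acta1, between 92.4 and 366 RPKM, and young bleomycin replicate 4 had Acta1 at 55.1 RPKM without Krt13. Krt13 and Acta1 were chosen after the values were seen. A list of fast skeletal muscle, also chosen afterwards, had 0 of 14 genes lower and 1 higher under bleomycin in young mice. In the planned list of cardiac and striated muscle 9 of 16 genes were lower, with Actc1 at −1.92 ± 0.39 and Tnni3 at −1.96 ± 0.47. Of 9 adipocyte genes 5 were lower, with Adrb3 at −1.54 ± 0.17. Adjusted over the list alone the counts were 9 and 5, and camera gave adjusted p = 0.00895 and 0.0076, or 0.706 and 0.544 with an estimated correlation.

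**Figure D1:**
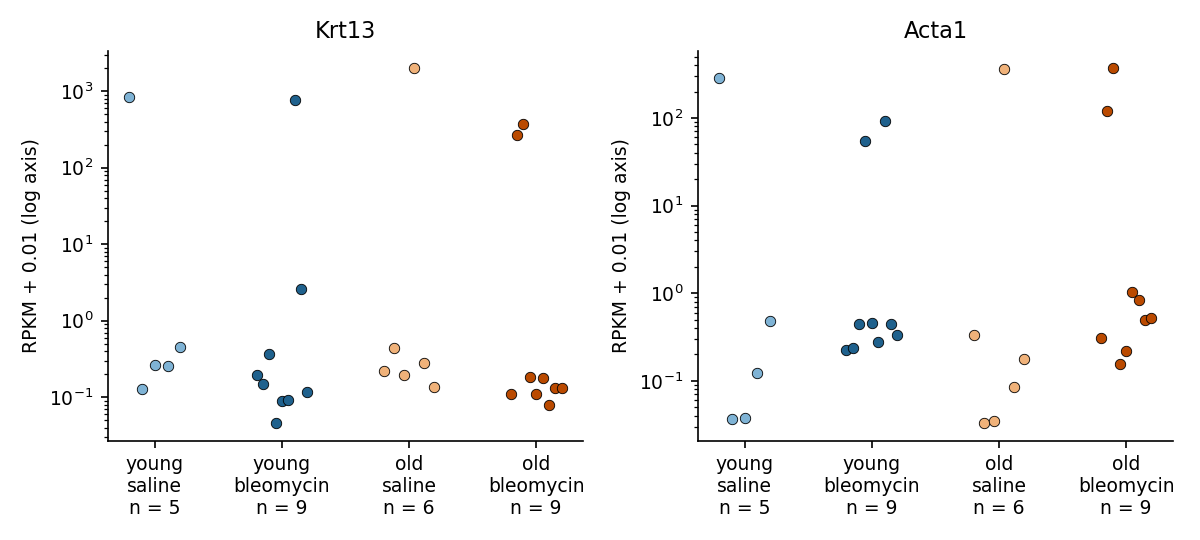
RPKM of the squamous keratin Krt13 and the skeletal-muscle actin Acta1 in each animal by group, as RPKM + 0.01 on a log axis. In 5 animals Krt13 is at 265 RPKM or above, and in the other 24 it is at 2.56 or below.

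The remaining 15 lists were not called by camera in young mice. Fry called the neutrophil (adjusted p = 0.00758), T-cell and NK-cell (0.047) and lymphoid chemokine lists (0.0353) among them. Alveolar type 2 genes split into 3 higher and 6 lower of 15 (10 over the list alone), with Cd74 at 0.71 ± 0.13 and Sftpa1 at −0.77 ± 0.19, and alveolar type 1 genes into 7 higher and 5 lower of 15, with Pdpn at 0.81 ± 0.08 and Cav1 at −0.54 ± 0.10. Alveolar macrophage genes split into 7 higher and 6 lower of 16, with Lpl at 1.39 ± 0.09 and Atp6v0d2 at 1.63 ± 0.13. Neutrophil genes had 6 of 10 lower and 1 higher, with Mmp9 at −1.77 ± 0.26. T-cell and NK-cell genes had 10 of 21 lower, with Prf1 at −1.37 ± 0.21 and Ncr1 at −1.40 ± 0.22, and 2 higher, among them Foxp3 at 0.91 ± 0.14. B-cell genes had 7 of 17 lower and 2 higher, with Cd79b at −1.06 ± 0.24 and Ms4a1 at −0.98 ± 0.23, and lymphoid chemokine genes 5 of 10 lower and 2 higher, with Cxcr5 at −1.06 ± 0.22. Basal-cell genes had 1 of 8 higher, Krt17 at 0.92 ± 0.21, and mesothelial genes 2 of 8 higher and 1 lower, with Msln at 1.37 ± 0.23.

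Metabolic, clock and blood-cell genes went both ways in young mice. Cholesterol genes had 2 of 17 higher and 4 lower, with Mvd at 0.62 ± 0.13, Insig1 at −0.57 ± 0.10 and Srebf2 at −0.38 ± 0.05. Oxidative phosphorylation genes had 6 of 20 higher and 3 lower, with Cox5a at 0.38 ± 0.09 and Uqcrq at 0.41 ± 0.10. Clock genes had 2 of 14 higher and 5 lower, with Bhlhe41 at 0.97 ± 0.13 and Arntl at −0.76 ± 0.13. Erythroid and platelet genes had 1 of 11 higher and 2 lower, with Ppbp at −1.50 ± 0.33 and Gp9 at −0.87 ± 0.22. Cartilage and thyroid genes had 1 of 3 higher, Comp at 0.74 ± 0.27, and 1 lower, and mast-cell and eosinophil genes 1 of 6 higher and 2 lower, with Cpa3 at −0.51 ± 0.19.

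The second question was what bleomycin does in old lungs. Of the 10 largest rises 8 were shared with young mice. Saa3 rose by 4.01 ± 0.42, Tnc by 3.84 ± 0.33, Grem1 by 3.76 ± 0.37, Timp1 by 3.16 ± 0.37, Trem2 by 2.85 ± 0.11, the collagen hydroxylase subunit P4ha3 by 2.82 ± 0.31, Cemip by 2.77 ± 0.43 and Thbs2 by 2.68 ± 0.35. Spp1 rose by 3.34 ± 0.16 (SE), from 119.3 ± 6.73 RPKM (SD, n = 6) to 1261 ± 375 (SD, n = 9), and Mmp12 by 3.20 ± 0.26, from 7.43 ± 3.45 to 73.4 ± 30.5 RPKM. Col1a1 rose by 2.22 ± 0.29 (from 76.0 ± 10.3 to 403 ± 209 RPKM), Col3a1 by 1.91 ± 0.20 and Fn1 by 2.48 ± 0.27. Mmp12, Spp1, Trem2, Col1a1, Timp1, Tnc and Cdkn2a were higher in 9 of 9 old bleomycin mice than in any old saline mouse.

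The largest falls in old mice were in Bex2 (−2.78 ± 0.22), Cst8 (−2.64 ± 0.25), Krt79 (−2.33 ± 0.28), Fabp1 (−2.19 ± 0.29), Ankrd63 (−2.10 ± 0.16), Slc7a10 (−2.07 ± 0.32), Gria1 (−2.02 ± 0.25), Slurp2 (−2.01 ± 0.27), Lypd2 (−1.90 ± 0.44) and Asgr1 (−1.90 ± 0.23). Arg1 (2.27 ± 0.42), Cthrc1 (1.16 ± 0.32), Krt8 (0.32 ± 0.09), Cdkn1a (0.72 ± 0.10), Cdkn2a (1.54 ± 0.16) and Gdf15 (0.48 ± 0.13) rose. Acta2 (−0.13 ± 0.16, adjusted p = 0.54), Sftpc (−0.32 ± 0.18, adjusted p = 0.17) and Ager (−0.11 ± 0.09, adjusted p = 0.32) did not pass. In all 7052 genes passed, 3188 higher and 3864 lower, with 523 changed at least 2-fold. With median-ratio scaling 3564 were higher and 3435 lower. Other splits of the animals reached at most 4606.

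Matrix, macrophage and transitional genes rose in old mice as well: 31 of 32 matrix genes (31 over the list alone), 19 of 22 fibrosis-associated macrophage genes with 1 lower (20 over the list alone; Gpnmb 2.57 ± 0.12) and 16 of 18 transitional epithelium genes (16 over the list alone; Clu 1.16 ± 0.10, Cldn4 1.86 ± 0.26). Cell-cycle genes had 20 of 22 higher, with Ube2c at 1.43 ± 0.17. Contractile and activated fibroblast genes had 15 of 22 higher, with Igf1 at 2.41 ± 0.16, although Acta2 did not pass. Complement genes had 13 of 16 higher, interferon genes 12 of 20 and p53 genes 11 of 18, with Psrc1 at 1.99 ± 0.14. Senescence genes had 13 of 21 higher and MHC class II genes 8 of 11, with Ctss at 2.25 ± 0.11. Each of these 7 lists had at most 2 lower. Adjusted over the list alone, 22, 19, 13, 14, 13, 15 and 9 members of these 7 lists passed. Lower were 11 of 15 general capillary genes (Tek −0.66 ± 0.08), 8 of 10 aerocyte genes (Ednrb −1.48 ± 0.16, Fibin −1.25 ± 0.12), 16 of 16 ciliated-cell genes, 5 of 15 club-cell genes, 10 of 14 lipofibroblast genes (Inmt −1.64 ± 0.20) and 8 of 16 immediate early and heat-shock genes, or 13, 9, 16, 5, 13 and 9 past the test either way adjusted over the list alone. Camera called these 16 lists, from adjusted p = 2.28e-19 for matrix to 0.0272 for club cells. With an estimated correlation none held in camera, the lowest being 0.0682 for macrophages, while fry called each of the 16.

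Of the 17 lists that camera did not call in old mice, fry called the neutrophil (adjusted p = 0.0162), erythroid and platelet (0.0259) and adipocyte lists (0.0458). Among the 17, 7 of 15 alveolar type 1 genes were lower and 1 higher (9 over the list alone), with Hopx at −0.74 ± 0.11 and Pdpn at 0.39 ± 0.07. T-cell and NK-cell genes had 5 higher and 5 lower of 21, with Foxp3 at 0.95 ± 0.14 and Ncr1 at −1.40 ± 0.21, and B-cell genes 8 of 17 lower. Cardiac and striated muscle genes had 1 of 16 lower (0 over the list alone) and adipocyte genes 2 of 9. Without the 6 animals with squamous or muscle transcripts camera called the muscle, adipocyte and alveolar type 1 lists at its preset correlation (adjusted p = 4.7e-05, 0.0141 and 0.0347). In all animals these lists were at 0.819, 0.772 and 0.808 with an estimated correlation, which was not run without the 6.

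**Figure D2:**
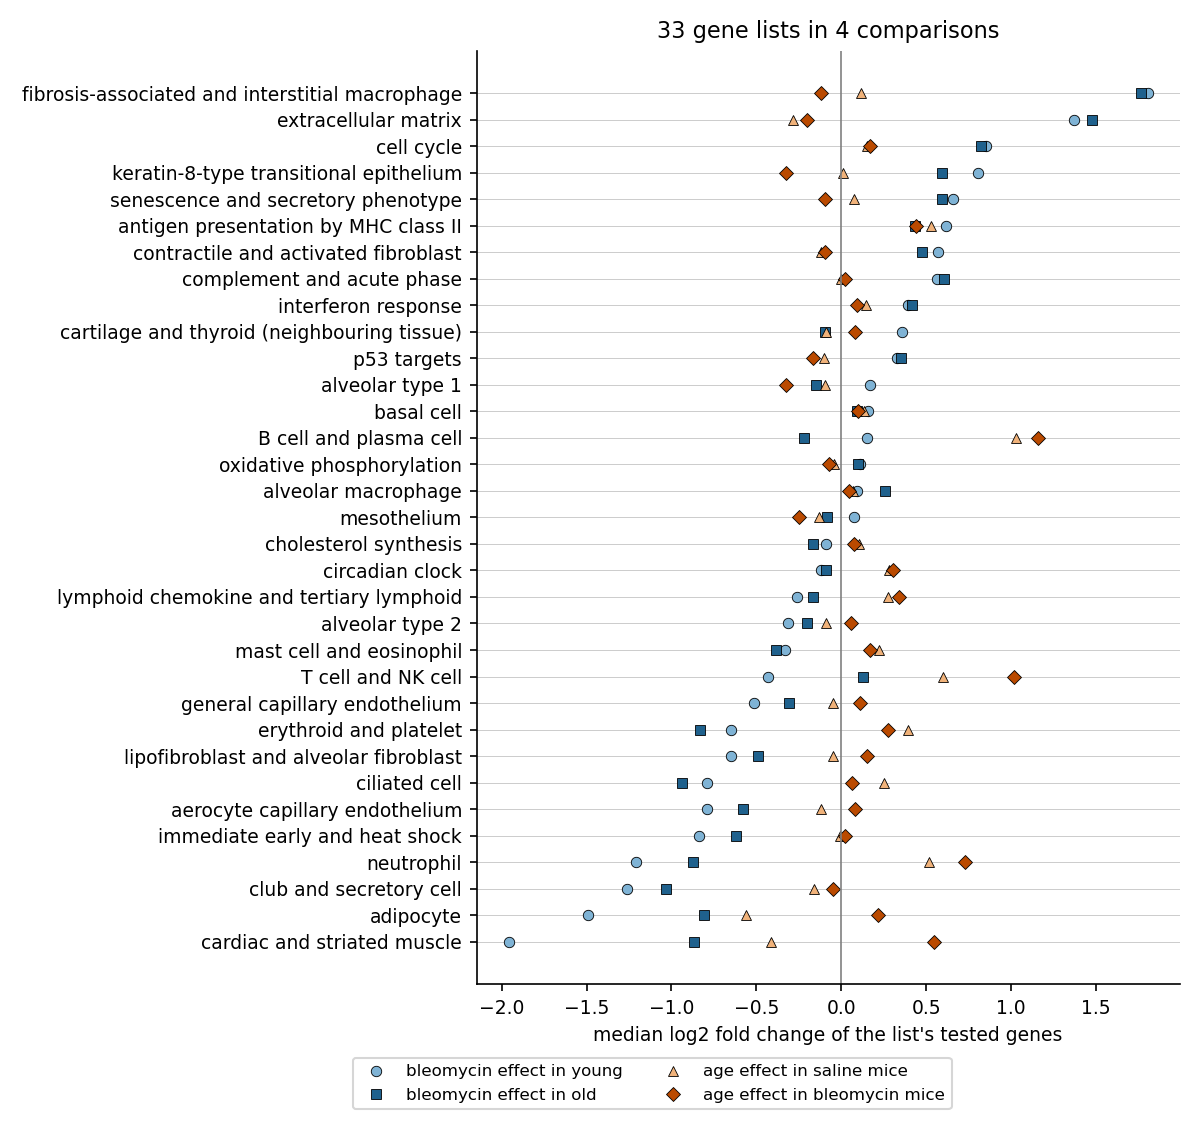
Median log2 fold change of the members of each of the 33 gene lists in 4 comparisons (bleomycin against saline in young and in old mice, old against young mice in saline and in bleomycin). The matrix list is at 1.37 in young and 1.48 in old mice under bleomycin.

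Young and old lungs answered bleomycin with mostly the same genes. Of the genes, 2640 were higher and 3025 lower at both ages, against 696 and 1018 for independent effects, and 5 went opposite ways. Across genes, which are not independent replicates, the fold changes of both ages had Pearson r = 0.90 and Spearman rho = 0.868, from animals that share no control. Of the miRNAs 22.5% were higher at both ages, against 7.9% for independent effects, 78 were lower against 21.8, and 0 went opposite ways (r = 0.877, rho = 0.861).

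The extracellular matrix score, the mean log2(RPKM + 0.5) of the 32 matrix genes, rose in young mice by 1.43 ± 0.14 (SE; 5 and 9 animals, exact two-sided permutation p = 0.0005) and in old mice by 1.53 ± 0.18 (6 and 9 animals, exact permutation p = 0.0004). Group means were 5.04 ± 0.09 (SD) in young saline, 6.47 ± 0.40 in young bleomycin, 4.76 ± 0.13 in old saline and 6.28 ± 0.53 in old bleomycin mice. Old and young bleomycin mice were not told apart (−0.18 ± 0.22, exact permutation p = 0.42), and the effects of bleomycin at the 2 ages differed by 0.10 ± 0.23 (permutation p = 0.69, 100000 resamples). In saline mice the scores of the ages did not overlap, between 4.91 and 5.14 in young and between 4.54 and 4.89 in old mice. No test of the score was run between the ages in saline mice.

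**Figure D3:**
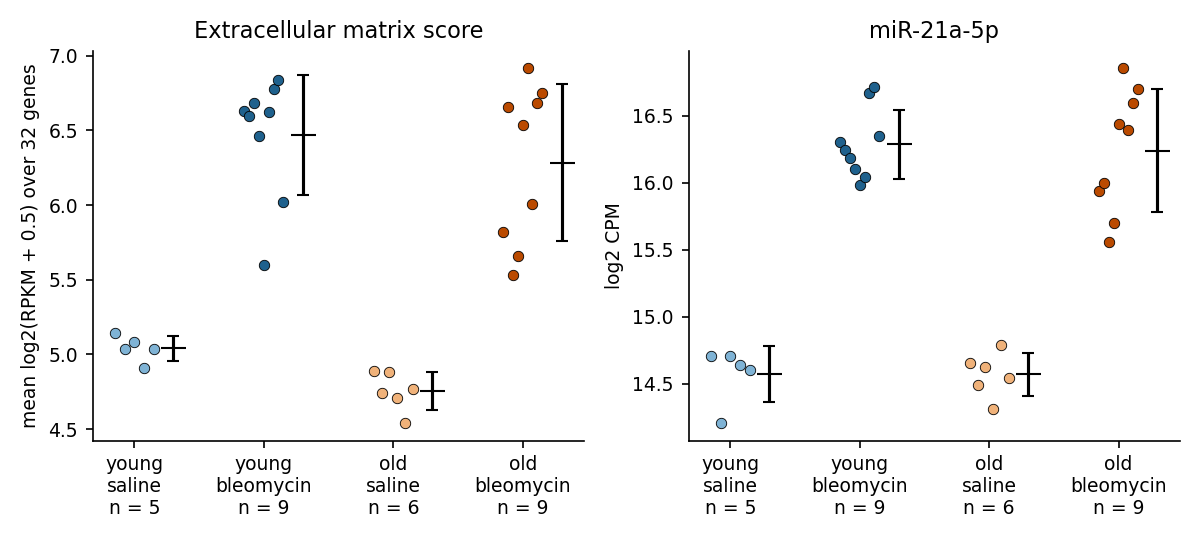
Extracellular matrix score (mean log2(RPKM + 0.5) of 32 genes) and miR-21a-5p (log2 CPM) of each animal by group, with the mean and SD. The score of bleomycin mice averages 6.47 in young and 6.28 in old mice, against 5.04 and 4.76 in saline mice.

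The third question was whether old lungs respond to bleomycin differently from young lungs. The chemokine Ccl9 (ENSMUSG00000019122, chromosome 11, 83572917–83578636) rose less in old mice. It went from 10.4 ± 0.864 to 63.9 ± 13.4 RPKM in young mice and from 18.5 ± 3.14 to 46.6 ± 9.41 in old mice (SD), log2 fold changes of 2.54 and 1.3 with a difference of −1.24 ± 0.20 (SE; adjusted p = 0.0174). D430019H16Rik (chromosome 12, 105453856–105493095), a gene outside the naming rule that was chosen after the values were seen, differed by 0.63 (adjusted p = 0.0193), at −0.45 in young and 0.18 in old mice. It did not pass under quantile normalization (0.124), without the 6 animals with squamous or muscle transcripts (0.196), or without young saline replicate 2 (0.0606) or 3 (0.0633) or old saline replicate 5 (0.0635), with the difference between 0.59 and 0.64 in these fits, whereas Ccl9 passed in each fit, with adjusted p between 0.00307 and 0.0497. These 2 of 16012 genes passed, against 1061 with an unadjusted p under 0.05. Other splits of the animals reached 1. Mmp12 (−1.78 ± 0.39, adjusted p = 0.13), Spp1 (−0.92 ± 0.23, adjusted p = 0.29), Krt8 (−0.38 ± 0.13, adjusted p = 0.48), Col1a1 (0.34 ± 0.42, adjusted p = 0.93) and Col3a1 (0.47 ± 0.28, adjusted p = 0.83) did not pass, so a different response of these genes was not shown. The count was 1 without young saline replicate 3 or old saline replicate 5, 6 without young bleomycin replicate 4, and 4 without young bleomycin replicate 9 or old bleomycin replicate 1, 4 or 9 or old saline replicate 6.

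In none of the 33 lists did a member pass for the difference over all genes. Adjusted over the list alone, 5 transitional epithelium genes, 5 fibrosis-associated macrophage genes and 4 alveolar type 1 genes passed, along with 2 T-cell genes and 1 each of the lipofibroblast, mesothelial and senescence lists. Camera put the alveolar type 1, transitional, macrophage, mesothelial and senescence lists lower and the T-cell, capillary, aerocyte, lipofibroblast, muscle and adipocyte lists higher in old mice, from adjusted p = 8.59e-07 for T cells to 0.0414 for senescence. With an estimated correlation all 11 were at 0.522 or above, and fry called 0.

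The fourth question was how old and young lungs differ without bleomycin. Plasma-cell and B-cell transcripts were higher in old saline mice. Ighm, the constant region of IgM, was at 156 ± 130 RPKM (SD, n = 5) in young and 991 ± 489 (SD, n = 6) in old mice, a log2 fold change of 2.87 ± 0.57 (SE; adjusted p = 0.0021). Jchain, which joins IgA and IgM units, was at 19.6 ± 17.7 and 114.4 ± 37.8 RPKM (2.87 ± 0.48, adjusted p = 6.1e-04). Both were higher in 6 of 6 old mice than in any young one. Ighg1 (3.64 ± 0.98), Ighg2c (3.63 ± 1.04), Ighg2b (2.94 ± 0.75), Igha (2.54 ± 0.59), Mzb1 (1.32 ± 0.37), the retinoic-acid hydroxylase Cyp26b1 (2.43 ± 0.55), the T-cell granzyme Gzmk (1.56 ± 0.40) and the clock output gene Dbp (1.38 ± 0.31) were also higher. All 44 of 176 receptor segments that passed were higher.

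Heat-shock genes were lower in old saline mice. Hspa1b (chromosome 17, 34956429–34959238) was at 40.5 ± 43.9 RPKM (SD) in young and 4.37 ± 5.88 in old mice, a log2 fold change of −2.97 ± 0.59 (SE), and its near-identical neighbour Hspa1a fell by 2.59 ± 0.46, with an uncertain split of reads between them. Hsph1 (−1.33 ± 0.39), Dnajb1 (−1.24 ± 0.20), Dnaja1 (−1.17 ± 0.24), Ahsa2 (−1.04 ± 0.24), Hspa8 (−0.92 ± 0.21) and Chordc1 (−0.89 ± 0.19) were lower too, as were Nr4a3 (−0.99 ± 0.20) and Npr3 (−0.97 ± 0.25). Whether handling of the ages differed in time is not stated in the labels. Of the genes followed in every comparison, Mmp12 (1.27 ± 0.30, adjusted p = 0.0087) and Spp1 (0.69 ± 0.18, adjusted p = 0.016) were higher in old mice and Cdkn1a was lower (−0.49 ± 0.11, adjusted p = 0.0048). Gdf15 was lower (−0.48 ± 0.14, adjusted p = 0.03) and Cdkn2a higher (0.75 ± 0.19, adjusted p = 0.011; 0.058 under quantile normalization). Col3a1 (−0.66 ± 0.22, adjusted p = 0.061) and Col1a1 (−0.57 ± 0.33, adjusted p = 0.32) did not pass, although Col1a1 did in a fit with only the compared groups. The SE comes from all 4 groups. The matrix score had an SD of 0.09 and 0.13 in saline mice against 0.4 and 0.53 in bleomycin mice. For matrix genes the SE may therefore overstate the spread of saline mice. Without the 6 animals with squamous or muscle transcripts Ighg1 (0.0969), Ighg2c (0.121), Hsph1 (0.0863), Npr3 (0.0524), Spp1 (0.0516) and Gdf15 (0.0565) no longer passed.

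Between the ages in saline mice 1570 genes passed, 1232 higher and 338 lower in old mice, with 83 changed at least 2-fold. Other splits reached at most 325. The share that was higher, 78.5%, depended on scaling. With median-ratio scaling 861 were higher and 608 lower (58.6%), and with quantile normalization 655 were higher and 759 lower (46.3%). The count fell to 968 without young saline replicate 4, to 981 without replicate 5 and to 762 without the 6 animals with squamous or muscle transcripts, and rose to 3153 with array weights. It was 2012 in a fit with only the compared groups.

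Lymphocyte genes were higher in old saline mice: 14 of 17 B-cell genes were higher (17 over the list alone), with Tnfrsf17 at 1.12 ± 0.16 and Cd22 at 1.03 ± 0.18, 12 of 21 T-cell and NK-cell genes (14 over the list alone), with Ccl5 at 1.23 ± 0.26, Cd8a at 1.00 ± 0.20 and Cd3e at 0.76 ± 0.16, and 8 of 11 MHC class II genes (10 over the list alone), with H2-Ob at 0.86 ± 0.23. Matrix genes had 4 of 32 lower (5 over the list alone), with Serpinh1 at −0.62 ± 0.16, Sparc at −0.41 ± 0.11 and Postn at −0.37 ± 0.10. Camera gave adjusted p = 1.6e-12, 6.16e-06, 6.16e-06 and 1.32e-06 for these 4, and with an estimated correlation 0.196, 0.759, 0.759 and 0.759. It also called contractile and activated fibroblast (0.0148), aerocyte (0.00277), p53 (0.0086) and immediate early and heat-shock genes (0.0131) lower. All 4 were at 0.759 with an estimated correlation, and none of them was called under quantile normalization. Among lists not called, 5 of 22 fibrosis-associated macrophage genes were higher, with Cx3cr1 at 0.69 ± 0.18 and Trem2 at 0.46 ± 0.12, and 4 of 14 clock genes were higher and 3 lower, with Nr1d2 at 0.96 ± 0.17 and Cry1 at −0.67 ± 0.13.

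The fifth question was how old and young lungs differ 21 days after bleomycin. T-cell transcripts were higher in old mice. Ccl5, a chemokine of effector T cells, was at 14.2 ± 2.94 RPKM (SD, n = 9) in young and 50.02 ± 20.8 (SD, n = 9) in old mice, a log2 fold change of 1.72 ± 0.20 (SE; adjusted p = 1.5e-06), and Gzmk rose by 2.08 ± 0.31 (adjusted p = 3.1e-05). Both were higher in 9 of 9 old mice than in any young one. Ighg2b (2.29 ± 0.59), Igha (1.90 ± 0.46) and Ighm (1.83 ± 0.45) were higher as in saline mice. Lower in old mice were Hspa1b (−2.06 ± 0.46), Hspa1a (−1.66 ± 0.36), Tnfsf18 (−1.24 ± 0.36), Hsph1 (−1.08 ± 0.30) and the imprinted gene Mest (−0.93 ± 0.20). Tnfsf18 did not pass without the 6 animals with squamous or muscle transcripts (0.115) or in a fit with only the compared groups (0.0648).

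Of the genes followed in every comparison, 4 were lower in old bleomycin mice: Krt8 (−0.36 ± 0.08, adjusted p = 0.0016) at 125 ± 14.4 RPKM (SD) in young and 97.2 ± 12.7 in old mice, Ager (−0.37 ± 0.08, adjusted p = 0.0021), Cdkn1a (−0.55 ± 0.09, adjusted p = 4.1e-05) and Gdf15 (−0.38 ± 0.11, adjusted p = 0.016). Cdkn1a was lower in 9 of 9 old mice than in any young one. Sftpc (−0.03 ± 0.16, adjusted p = 0.922), Cdkn2a (0.37 ± 0.15, adjusted p = 0.073), Mmp12 (−0.51 ± 0.24, adjusted p = 0.13) and Col1a1 (−0.23 ± 0.26, adjusted p = 0.57) did not pass. Old mice had received a lower dose, and Krt8 and Ager did not pass between the ages in saline mice, so age and dose cannot be separated for these. Cdkn1a and Gdf15 were also lower in old saline mice, which received no bleomycin. In all 3290 genes passed, 2459 higher and 831 lower in old mice, with 151 changed at least 2-fold, and other splits reached at most 784. The share that was higher, 74.7%, was 50.2% with median-ratio scaling (1675 higher, 1662 lower) and 44.9% with quantile normalization (1280 higher, 1572 lower). In a fit with only the compared groups 2538 genes passed. All 85 of 176 receptor segments that passed were higher.

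All 17 B-cell genes were higher in old bleomycin mice (17 over the list alone), as were 17 of 21 T-cell and NK-cell genes (18 over the list alone), with Cd8a at 1.57 ± 0.15, Lck at 1.19 ± 0.12 and Cd3e at 1.17 ± 0.12, 9 of 11 MHC class II genes (10 over the list alone), with H2-Ob at 1.07 ± 0.18, and 5 of 10 lymphoid chemokine genes (6 over the list alone), with Cxcr5 at 1.19 ± 0.19 and Ltb at 0.82 ± 0.13. Lower were 11 of 15 alveolar type 1 genes (11 over the list alone), with Scnn1g at −0.40 ± 0.06, Pdpn at −0.36 ± 0.07 and Gprc5a at −0.32 ± 0.05, 8 of 18 transitional genes (9 over the list alone), with Krt7 at −0.40 ± 0.08, 7 of 18 p53 genes (11 over the list alone), with Ccng1 at −0.31 ± 0.04, and 4 of 8 mesothelial genes (4 over the list alone), with Msln at −0.75 ± 0.20 and Wt1 at −0.47 ± 0.17. Camera gave these 8 lists adjusted p = 6.57e-11, 1.8e-14, 3.89e-04, 0.00349, 6.57e-11, 1.21e-09, 6.44e-06 and 6.81e-04, and with an estimated correlation the lowest was 0.131.

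The other 6 lists that camera called lower in old bleomycin mice were not called under quantile normalization. These were matrix (adjusted p = 5.98e-04; Mfap4 0.48 ± 0.08 and Postn −0.34 ± 0.08), contractile and activated fibroblast (0.0341), fibrosis-associated macrophage (0.0171; Cx3cr1 0.40 ± 0.14), senescence (0.0217), oxidative phosphorylation (0.0217) and immediate early and heat-shock genes (0.0199). With an estimated correlation all were at 0.838 or above. The last had 4 of 16 members lower, with a mean log2 fold change of −0.31 and a median of 0.02. Among lists not called, clock genes had 6 of 14 higher and 4 lower, with Dbp at 1.65 ± 0.24, Arntl at −0.50 ± 0.11 and Cry1 at −0.48 ± 0.10, and neutrophil genes 3 of 10 higher, with Retnlg at 1.27 ± 0.27 and Mmp9 at 0.93 ± 0.22.

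The same 5 questions were asked of miRNAs. In young mice miR-184-3p, a miRNA of epithelia, rose most under bleomycin, from 3.83 ± 1.01 CPM (SD, n = 5) to 39.7 ± 5.62 (SD, n = 9), a log2 fold change of 3.37 ± 0.22 (SE; adjusted p = 6.8e-13). It was followed by miR-7b-5p (2.83 ± 0.30), miR-147-3p (2.57 ± 0.25), miR-298-5p (2.53 ± 0.36), miR-1983 (2.49 ± 0.26), miR-147-5p (2.29 ± 0.33), miR-21a-3p (2.10 ± 0.34), miR-146b-3p (1.97 ± 0.17), miR-212-5p (1.96 ± 0.30) and miR-146b-5p (1.85 ± 0.14). The largest falls were in miR-1298-5p (−1.60 ± 0.24), miR-1912-3p (−1.51 ± 0.28), miR-1912-5p (−1.49 ± 0.36), miR-1298-3p (−1.40 ± 0.25), miR-676-5p (−1.25 ± 0.16), miR-1264-3p (−1.19 ± 0.23), miR-676-3p (−1.15 ± 0.12), miR-448-3p (−1.15 ± 0.24), miR-208b-3p (−0.97 ± 0.23) and miR-33-5p (−0.93 ± 0.25). Of 519 miRNAs 249 passed, 146 higher and 103 lower (58.6% higher), with 70 changed at least 2-fold. Scaled by library totals alone 228 passed, 171 higher and 57 lower. Other splits reached at most 60.

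In old mice miR-298-5p (3.08 ± 0.43), miR-7b-5p (2.67 ± 0.27), miR-147-3p (2.61 ± 0.23), miR-147-5p (2.24 ± 0.30), miR-184-3p (2.24 ± 0.19), miR-21a-3p (2.12 ± 0.32), miR-1983 (1.98 ± 0.24), miR-212-3p (1.95 ± 0.29), miR-376a-3p (1.91 ± 0.49) and miR-146b-3p (1.83 ± 0.16) rose most. The largest falls were in miR-1298-3p (−1.42 ± 0.22), miR-1298-5p (−1.31 ± 0.23), miR-351-3p (−1.27 ± 0.21), miR-322-3p (−1.27 ± 0.16), miR-503-3p (−1.25 ± 0.17), miR-676-3p (−1.25 ± 0.12), miR-448-3p (−1.19 ± 0.22), miR-1264-3p (−1.16 ± 0.22), miR-375-3p (−1.12 ± 0.25) and miR-1912-3p (−1.08 ± 0.28). In all 256 passed, 146 higher and 110 lower (57.0%), with 62 changed at least 2-fold. Scaled by library totals alone 269 passed, 211 higher and 58 lower (78.4%). Other splits reached at most 168.

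**Figure D4:**
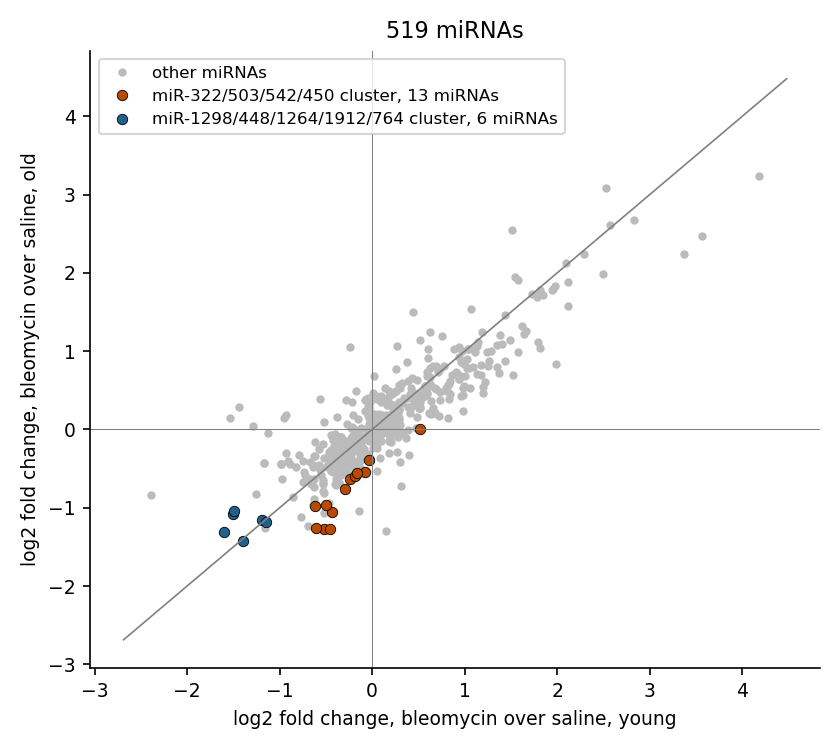
Log2 fold change under bleomycin of the 519 miRNAs in young (horizontal) and old (vertical) mice with the identity line, and with the 13 miRNAs of the miR-322 cluster and the 6 of the miR-1298 cluster marked. Across miRNAs Pearson r is 0.877.

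Known fibrosis miRNAs changed at both ages. Of 20 miRNAs raised in fibrosis models 16 were higher and 2 lower in young mice (19 over the list alone), with miR-21a-5p at 1.72 ± 0.18 and miR-34a-5p at 1.14 ± 0.11, and 16 were higher and 1 lower in old mice (17 over the list alone). The miR-29 family, which targets collagen transcripts, had 6 of 7 members lower in young mice, with miR-29c-3p at −0.74 ± 0.12, and 5 in old mice, with miR-29a-3p at −0.63 ± 0.09. The miR-30 and let-7 families had 9 of 16 lower in young mice, with miR-30c-5p at −0.42 ± 0.10, and 13 in old mice, with miR-30a-3p at −0.81 ± 0.12. The imprinted Dlk1-Dio3 miRNAs had 26 of 29 higher in young mice, with miR-494-3p at 1.64 ± 0.24 and miR-382-5p at 1.18 ± 0.16, and 20 in old mice. Adjusted over the list alone, 6, 11 and 28 members of the last 3 lists passed in young and 5, 14 and 22 in old mice. Camera gave these 4 lists adjusted p = 7.6e-06, 0.00152, 0.0145 and 1.5e-07 in young and 9.38e-07, 0.0194, 1.48e-04 and 3.81e-05 in old mice, and with an estimated correlation none was under 0.0735. It also called the miR-200 family (0.0262; 4 of 9 lower, miR-200a-3p −0.52 ± 0.12) and muscle miRNAs (0.0262; 1 of 9 lower) in young mice, both at 0.43 with an estimated correlation.

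The other lists of miRNAs were not called by camera under bleomycin. In young and old mice fry called the haematopoietic (adjusted p = 0.00105 and 0.0113), endothelial (0.00367 and 3.99e-06) and miR-183 lists (2.05e-04 and 0.0448). Haematopoietic miRNAs had 7 of 15 higher and 3 lower in young mice, with miR-342-3p at 1.01 ± 0.14 and miR-511-3p at 1.41 ± 0.21. Endothelial miRNAs had 2 of 4 lower at either age, with miR-126a-3p at −0.32 ± 0.07 in young and −0.41 ± 0.07 in old mice. In the miR-34 and miR-449 families miR-449a-5p rose by 0.62 ± 0.21 and 1.24 ± 0.20 and miR-34b-3p fell by 0.64 ± 0.25 and 0.97 ± 0.23. In the miR-17-92 group 2 of 16 were higher and 2 lower in young mice, with miR-92a-3p at −0.56 ± 0.13. In the miR-183 cluster 2 of 4 were higher in young mice, with miR-183-5p at 0.52 ± 0.10, and 0 of 4 erythroid miRNAs passed, with miR-486-5p at −0.99 ± 0.61.

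For the difference between ages 0 of 519 miRNAs passed, with 28 at an unadjusted p under 0.05. DESeq2 gave 0, voom with quality weights 1, and the test without a filter 1, while other splits of the animals reached 11. Camera called the miR-30 and let-7 list (adjusted p = 0.014) and the Dlk1-Dio3 list (0.0112) lower and muscle miRNAs (0.014) higher in old mice, at 0.537, 0.593 and 0.537 with an estimated correlation.

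In saline mice miR-155-5p (0.91 ± 0.25), miR-184-3p (0.88 ± 0.23), miR-130b-5p (0.85 ± 0.21), miR-150-5p (0.85 ± 0.22) and miR-215-5p (0.76 ± 0.19) were higher in old animals. Lower were miR-551b-3p (−1.89 ± 0.40), miR-298-5p (−1.80 ± 0.51), miR-450a-5p (−0.96 ± 0.21), miR-381-3p (−0.94 ± 0.27) and miR-542-3p (−0.91 ± 0.15, adjusted p = 3e-04). The lymphocyte miRNA miR-150-5p was at 1601 CPM in young and 2880 in old mice. In all 43 passed, 24 higher and 19 lower (55.8%), with 3 changed at least 2-fold. Scaled by library totals alone 29 passed, 12 higher and 17 lower (41.4%). Other splits reached 1. The count was 16 without young saline replicate 4, 18 without young saline replicate 1, and 21, 25 and 26 without old saline replicates 4, 1 and 5. It was 23 without a filter and 84 by voom with quality weights. Without the 6 animals with squamous or muscle transcripts the count was 13, and miR-184-3p (0.109), miR-130b-5p (0.0635), miR-150-5p (0.148), miR-298-5p (0.0643) and miR-381-3p (0.13) no longer passed.

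In bleomycin mice miR-6240 (0.98 ± 0.29), miR-150-5p (0.82 ± 0.17), miR-106a-5p (0.78 ± 0.16), miR-20b-5p (0.77 ± 0.13) and miR-363-3p (0.71 ± 0.23) were higher in old animals. Lower were miR-450a-5p (−1.34 ± 0.17), miR-542-3p (−1.32 ± 0.12, adjusted p = 1.1e-09), miR-450a-1-3p (−1.31 ± 0.24), miR-322-5p (−1.3 ± 0.10, adjusted p = 3.8e-11) and miR-551b-3p (−1.26 ± 0.26). MiR-322-5p was at 2747 ± 502.6 CPM (SD, n = 9) in young and 1115 ± 186 (SD, n = 9) in old mice, lower in 9 of 9. In all 73 passed, 22 higher and 51 lower (30.1%), with 16 changed at least 2-fold, and 110 without old bleomycin replicate 6. It was 42 with a minimum count of 100, 110 by voom with quality weights and 43 without the 6 animals with squamous or muscle transcripts. Scaled by library totals alone 85 passed, 36 higher and 49 lower (42.4%). Other splits reached at most 46.

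Of 15 haematopoietic miRNAs 4 were higher in old saline mice (6 over the list alone; miR-142-5p 0.63 ± 0.13) and 4 in old bleomycin mice (miR-142-5p 0.56 ± 0.10), as were 3 and 4 of 16 miRNAs of the miR-17-92 group, with miR-92a-3p at 0.58 ± 0.14 in saline. Of 29 Dlk1-Dio3 miRNAs 1 was lower in old saline mice and 16 in old bleomycin mice (25 over the list alone; miR-154-5p −0.65 ± 0.15). Camera gave adjusted p = 0.0114, 0.0218 and 0.0218 in saline and 0.00388, 7.46e-04 and 4.48e-09 in bleomycin mice, and with an estimated correlation none was under 0.112. In saline mice it also called the miR-30 and let-7 list higher (0.0455, or 0.481 with an estimated correlation).

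Within groups, 4 miRNAs were set against the matrix score, 8 relations in all, each over 9 animals. In old bleomycin mice miR-21a-5p rose with the score (Pearson r = 0.85, exact permutation p = 0.0076, adjusted 0.03, and Spearman rho = 0.95, exact permutation p = 0.00035, adjusted 0.0028). In young bleomycin mice miR-199a-5p did (r = 0.87, exact permutation p = 0.0017, adjusted 0.013, and rho = 0.75, exact permutation p = 0.025, adjusted 0.1). Without the 2 animals farthest from the median r was 0.67 (exact permutation p = 0.091) and 0.69 (exact permutation p = 0.052), so neither Pearson relation passed without them, while rho was 0.89 for miR-21a-5p and 0.54 for miR-199a-5p. With library totals only, miR-199a-5p kept r = 0.75 without those animals (exact permutation p = 0.027). The other 6 relations, of miR-29a-3p and miR-34a-5p at both ages, miR-21a-5p in young and miR-199a-5p in old mice, did not pass.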

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

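The tests of squamous and muscle transcripts, of heat-shock transcripts and of the excess of higher genes were chosen after those results were seen, while the splits of the animals were planned.

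Values of single animals stood apart in 60 of 868 groups of named genes and miRNAs (6.9%), where chance gives about 1 in 20. Of the 60, 7 are for Krt13, Acta1 and miR-205-5p, which were chosen because they stood apart. Each value below is the gap between that animal and its nearest neighbour as a share of the range of its group.

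Old saline replicate 2 stood apart most often. It was the highest of its group for the chaperone genes Hspa1b (0.787), Hspa1a (0.756), Hspa8 (0.714), Hsph1 (0.713), Chordc1 (0.698), Ahsa2 (0.694), Serpinh1 (0.690) and Dnaja1 (0.645), and for Npr3 (0.783) and Cry1 (0.641). Old saline replicate 5 was highest for Tppp3 (0.637), miR-1298-3p (0.764) and miR-30a-3p (0.709) and lowest for miR-494-3p (0.663). Replicate 4 was highest for miR-206-3p (0.867) and miR-150-5p (0.722) and lowest for Postn (0.688). Replicate 1 was highest for Cxcl10 (0.778) and lowest for miR-448-3p (0.706), and replicate 6 was highest for Actc1 (0.659) and lowest for Ltb (0.787).

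Young saline replicate 1 was highest for miR-206-3p (0.839), Arg1 (0.760), miR-133a-3p (0.740) and Mb (0.713), and lowest for Ankrd63 (0.873) and miR-1264-3p (0.863). Replicate 3 was highest for Cyp1a1 (0.871). Replicate 2 was highest for Prf1 (0.741) and lowest for miR-21a-5p (0.793). Replicate 5 was highest for Cdk1 (0.777) and Nr4a3 (0.733), and replicate 4 was highest for miR-450a-5p (0.732) and lowest for AA467197 (0.803).

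Young bleomycin replicate 7 was highest for miR-382-5p (0.679), Cnn1 (0.586), miR-154-5p (0.543), miR-155-5p (0.526) and Comp (0.522), and lowest for Cav1 (0.715) and miR-30a-3p (0.498). The lowest values for Cd74 (0.602), Fibin (0.553), Mest (0.540), Ighg2c (0.512) and Gp9 (0.505) were in replicates 8, 9, 5, 2 and 6. Among old bleomycin mice, replicate 9 was highest for Cyp1a1 (0.786) and Lck (0.499) and lowest for miR-375-3p (0.696). Replicate 2 was highest for Tnni3 (0.650), replicate 1 for Retnlg (0.649) and replicate 8 for miR-183-5p (0.613), and replicate 8 was lowest for miR-106a-5p (0.577).

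The squamous keratin Krt13 was highest in young saline replicate 1 (0.942), young bleomycin replicate 7 (0.761) and old saline replicate 4 (0.951). Acta1 was highest in the same 2 saline mice (0.903 and 0.930), and miR-205-5p in young saline replicate 1 (0.890) and young bleomycin replicate 7 (0.539).

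The effect of bleomycin differed between the ages for the chemokine Ccl9 (−1.24, adjusted p = 0.0174) and for D430019H16Rik (0.63, adjusted p = 0.0193). Ccl9 rose at both ages, in 9 of 9 mice each time, and rose less in old mice, which had received a lower dose. Its mean in saline mice, which got no dose, was higher in old than in young mice, and this level enters the difference too. D430019H16Rik did not pass under quantile normalization (adjusted p = 0.124) or without the 6 animals with squamous or muscle transcripts (0.196), with the difference still at 0.63 and 0.64.

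Squamous keratin and skeletal-muscle transcripts appeared together in 5 animals. These were also the 5 of 29 with the most miR-205-5p, a miRNA of squamous and basal epithelium, in libraries made separately for miRNA. Tissue of another organ in the frozen powder would give such a match. MiR-205-5p was chosen because it stood apart, so the match is no independent test. Mixing of libraries was argued against by the ratio of Krt13 to Acta1, which varied 8.27-fold between the 5. A bleomycin-driven squamous change of the airway as the whole source was argued against by the 2 saline mice among them. The organ, if it was one, and the step at which its tissue entered stay open.

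Heat-shock transcripts, in a list of 16 genes chosen after the data were seen, were lower in old mice given saline (11 of 16, median −0.76) or bleomycin (11 of 16, median −0.52). Fry gave adjusted p = 0.00145 and 0.00452, and camera with an estimated correlation 0.0566 and 0.183. With a list chosen from these same data, such p-values are no independent test. The planned list of immediate early and heat-shock genes had 4 of 16 lower in saline mice, with a median of −0.01. Leaving out the 6 animals with squamous or muscle transcripts left the median in bleomycin mice at −0.56, with Hspa1a and Hspa1b past the threshold. This argues against other tissue as the whole cause. Quantile normalization left the median at −0.52, with both genes past the threshold. It moved the median of all genes only from 0.045 to −0.027, too little to remove a fall of that size, so it does not decide about scaling. The heat-shock score had r = 0.34 with the animal number in young bleomycin mice (n = 9, exact permutation p = 0.38), −0.04 in old bleomycin (n = 9, exact permutation p = 0.92) and −0.37 in old saline mice (n = 6, exact permutation p = 0.58). In the 5 young saline mice, too few for a correlation, the score was 5.64, 5.41, 5.71, 6.31 and 6.82 in order of animal number, and numbers of young and old animals do not overlap. Separate handling and age therefore cannot be told apart, and a lower heat-shock response in old lungs stays untested.

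More genes were higher than lower in old bleomycin mice. Among the 3139 genes changed less than 2-fold 73.7% were higher, and 43.0% were under quantile normalization, so scaling of the libraries may account for the excess, although this normalization also removes a real small shift. A minimum RPKM of 2 left 71.4%, which argues against genes near the detection floor. Among the 151 genes changed at least 2-fold 96% were higher, and of the 112 such genes under quantile normalization 92% were. That normalization moved the median of all genes only from 0.045 to −0.027. It could hardly have reversed changes of 2-fold, so it does not decide about scaling for these. Of the 145 genes at least 2-fold higher as deposited, 90 also passed as higher in old saline mice, which got no dose. The median log2 fold change of the 145 was 1.03 there against 1.41, which argues against the lower dose of old mice as the whole cause.

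Other splits of the same animals, 100 for each comparison with the real one included, showed where chance can be excluded at a level of 1 in 100. More splits are possible than were run, so a rarer chance result is not excluded. As many genes as in the real groups came from 1 of 100, the real split alone, in each comparison: 7715 against at most 3253 elsewhere for bleomycin in young mice, 7052 against 4606 in old mice, 2 against 1 for the difference, 1570 against 325 for age in saline and 3290 against 784 for age in bleomycin mice. At that level chance can be excluded for the 4 comparisons other than the difference. For the difference, 2 genes against 1 is a narrow gap, and its splits mixed the ages within each treatment. They therefore remove any effect of age, not the difference alone, and chance is not excluded there. The count was 1 without young saline replicate 3 or old saline replicate 5 and without the 6 animals with squamous or muscle transcripts, and no splits were run in those fits. For miRNAs it can be excluded for bleomycin in young mice (249 against 60; 1 of 100), in old mice (256 against 168; 1 of 100), and age in saline (43 against 1; 1 of 100). For age in bleomycin mice (73 against 46; 1 of 100) it can be excluded with all animals and the planned filter. The count was 43 without the 6 animals and 42 at a minimum count of 100, and no splits were run in those fits. For the difference 0 miRNAs passed, against at most 11 elsewhere, so each of the 100 splits gave as many (100 of 100) and the splits decide nothing. The median over the other splits was 0 genes and 0 miRNAs in each comparison.

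Chance could not be excluded for any count of lists called by camera at its preset correlation. For gene lists 9, 46, 50, 58 and 41 of 100 splits gave as many in the 5 comparisons, with 18, 16, 11, 8 and 14 lists in the real groups and at most 21, 23, 18, 19 and 21 elsewhere. For miRNA lists 15, 34, 35, 6 and 62 of 100 splits did, with 6, 4, 3, 4 and 3 lists in the real groups and at most 7, 8, 6, 5 and 6 elsewhere.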

How the results depend on the processing

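The fit without the 6 animals with squamous or muscle transcripts was chosen after the data were seen, and the other alternatives were planned.

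The bleomycin counts were stable with each library left out. For mRNA they stayed between 6881 and 8031 in young and between 6348 and 7329 in old mice, and for miRNA between 219 and 256 and between 227 and 256. Other settings went outside these ranges. Array weights gave 8408 genes in young and 8221 in old mice. Voom with quality weights gave 324 miRNAs in young and 247 in old mice, and a minimum count of 100 gave 166 and 180. The rise of the matrix score stayed past its test at both ages under each alternative run. Of the genes and miRNAs named, 0 reversed direction after being called.

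Counts for age and for the difference between the ages moved more. With each library left out, genes for the difference ranged from 1 to 6 around 2 and those for age in saline mice from 968 (without young saline replicate 4) to 1936 around 1570. For miRNAs the difference ranged from 0 to 1, age in saline mice from 16 (without young saline replicate 4) to 53 around 43, and age in bleomycin mice from 64 to 110 (without old bleomycin replicate 6) around 73. Array weights gave 9 genes for the difference and 3153 for age in saline mice, and voom with quality weights gave 1, 84 and 110 miRNAs for the difference, age in saline and age in bleomycin mice. Both kinds of weights count noisy libraries less, and the cause was not tested further.

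Without the 6 animals, fewer samples were tested, and the counts were 1 and 762 genes for the difference and age in saline, 13 and 43 miRNAs for age in saline and in bleomycin, and 2 miRNA lists for age in saline. Without a filter the miRNA test gave 1 for the difference and 23 for age in saline mice. A minimum count of 100, which leaves fewer miRNAs to test, gave 42 for age in bleomycin mice. At an adjusted p under 0.01 the genes lower at both ages went from 3025 to 1957 and the miRNAs from 78 to 47, as a stricter threshold must lower them.

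With an estimated correlation camera called 0 gene lists and 0 miRNA lists in each of the 5 comparisons, a setting that allows for genes of a list that vary together. Fry called 21 and 19 gene lists for bleomycin in young and old mice, 0 for the difference, 4 for age in saline and 9 for age in bleomycin mice. Of the miRNA lists it called 9 and 8 for bleomycin in young and old mice, 0 for the difference, and 4 and 3 for age. Fry asks another question than camera, so its counts are not a repeat.

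Among single genes and miRNAs in each comparison, 29248 checks with a library left out gave the same verdict, past the threshold or not. In 400 checks a call was lost, and in fewer a call was gained. The 29248 include genes and miRNAs that passed in neither fit, so these numbers do not give the share of calls lost. Over 745 such checks of genes, quantile normalization lost 22 calls and gained 5, and median-ratio scaling lost 12 and gained 11. Library totals alone lost 17 and gained 6 miRNA calls. Without the 6 animals 59 were lost and 11 gained. The depth of the mRNA libraries is unknown, and the lower miRNA depth of old bleomycin mice limits what can be said of scarce miRNAs there.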

Other observations

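The lists of immediate early genes, of heat-shock genes alone, of the miR-322 and miR-1298 clusters and of squamous and fast-muscle transcripts were chosen after the data were seen. So was the pairing of miRNAs with the genes that contain them. The p-values of these lists are therefore no independent test.

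The X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450 (GRCm38 chromosome X, from 53047997 to 53054349), whose miRNAs restrain the cell cycle, was lower in old mice. All 13 tested members were lower in old than in young bleomycin mice (median −1.15; fry adjusted p = 2.5e-10, and 2.5e-04 for camera with an estimated correlation), and 7 were in saline mice (median −0.76; 5.1e-04 and 0.0363). Under bleomycin 10 fell in old mice (median −0.76; 2.7e-06 and 0.0964), while 3 fell and 1 rose in young mice (median −0.29; 0.0751 and 0.517). MiR-322-5p itself rose by 0.52 in young mice and was at 0.00 in old mice. The difference between the ages had a median of −0.47 (0.0197 and 0.0451), with 0 single members past the test. The cluster was chosen after the data were seen, with members among the largest falls with age, so its p-values are no independent test.

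The miR-1298, miR-448, miR-1264 and miR-1912 cluster lies inside Htr2c (chromosome X, 146962464–147197277). All 6 tested members fell under bleomycin in young mice (median −1.45; fry adjusted p = 6.2e-06, and 0.135 for camera with an estimated correlation) and in old mice (median −1.17; 3.4e-06 and 0.0964). This cluster was chosen after the data were seen, with members among the largest falls under bleomycin at both ages. Neither the count of members nor the p-values are therefore an independent test.

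Many miRNAs moved with the gene that contains them. Over 169 pairs in 140 genes, log2 fold changes under bleomycin had Pearson r = 0.66 in young and 0.66 in old mice (Spearman rho 0.56 and 0.55), across pairs that are not independent. For age r was 0.36 in saline and 0.37 in bleomycin mice (rho 0.22 and 0.14). Where both passed, 14 were higher together, 20 lower together and 5 opposite in young mice, and 19, 21 and 7 in old mice. MiR-147-3p rose by 2.57 and 2.61 with AA467197 (3.04 and 2.31), miR-21a-5p by 1.72 and 1.73 with Vmp1 (0.83 and 0.74), miR-335-5p by 1.03 and 0.90 with Mest (1.47 and 1.29) and miR-511-3p by 1.41 and 1.1 with Mrc1 (1.04 and 0.86), in young and old mice. MiR-676-3p fell with Eda, by 1.15 and 1.25 against 0.79 and 0.64. No strand was available, so containing means overlap of positions alone.

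Immediate early genes, which respond to stimuli within minutes, were lower after bleomycin: 8 of 12 fell and 3 rose in young mice (median −0.75; fry adjusted p = 6.1e-04), and 8 fell and 1 rose in old mice (median −0.68; 1.5e-04). With an estimated correlation camera gave 0.895 and 0.688. Of the squamous list 2 of 25 tested genes and of the fast-muscle list 1 of 14 passed under bleomycin at either age, all higher.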
